A study of Mus musculus with 2 samples.

How the data were processed

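ATAC-seq, in which the Tn5 transposase inserts adapters into open chromatin, was run on 2 samples of mouse Stag3 KO GSCs, numbered replicate 1 and replicate 2 in their titles. Per the labels' protocols, sorted reporter-positive viable cells were permeabilised, transposed and amplified by PCR. Both samples formed 1 group; group and replicate came from the labels. The submitters' processing notes name Trim Galore, Bowtie2 2.3.4.1, Picard 2.18.23, bedtools 2.29.2, MACS2 2.1.1 and deepTools 3.5.0, and the builds GRCm38.p3 and mm10. Their settings, including any shift of reads for the Tn5 insertion site, duplicate removal and removal of problem regions, were not given in the sources used here. Such steps set which sites reach the threshold and how sharp the summits are.

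The deposited files were peak lists, with 1 list per sample, so peaks had been called per sample and not on pooled reads. Each peak had a fold enrichment over the local background, which is the ratio the authors' peak caller gave. It also had a −log10 p-value and a −log10 q-value as the authors deposited them, and a deposited score that was 10 times the −log10 q-value cut to a whole number. The smallest −log10 p-value was 4.01 and 4.12, and −log10 q reached 5 or more in 97.3% of peaks of each list. Fold enrichment itself was used to describe, rank and filter peaks within a list, and with the p-value to recover tags, which were compared between libraries and chromosomes. No peaks overlapped within a list, and all lay on chromosomes 1 to 19, X or Y. The score column was not used further.

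Read depth was unknown, but the tags at each summit were recovered. The fold was taken as tags plus 1 over background plus 1, and the p-value as the Poisson tail above the tag number. A unique whole number solved both equations for 100% of peaks in each list, within a relative tolerance of 1e-05 plus 0.0001 on the −log10 scale. The lowest background was 2.19 tags in replicate 1 and 2.13 tags in replicate 2. Intervals are 95% Wilson intervals and cover counting error only, since PCR copies and neighbouring sites are not independent.

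Peaks counted as shared when they overlapped by at least 1 bp. A shared region joined a replicate 1 peak with the replicate 2 peak that overlapped it most. Replicate 1 peaks with the same partner gave separate regions, which can overlap and were each counted. A shared region counted as a gene-end peak in both libraries when any part of it lay in the window, even if only 1 of its peaks did. Chance was the mean of 20 seeded random placements of the peaks between the first and last gene or peak of each chromosome. Genes came from a RefSeq table on GRCm38.p6, whose chromosomes have the coordinates of the build of the peaks; 21887 protein-coding genes lay on the chromosomes used. The table as used here holds gene starts and ends only. The planned promoter, a transcription start with 1000 bp on each side, was therefore replaced by 1000 bp on each side of both gene ends. This includes 3′ ends and misses start sites inside a longer model. Exons, introns, start sites at the 5′ end and all motif analysis needed data not used here and were left out.

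The gene lists, their main test, the planned windows and the rule for named genes were fixed before the data were examined. The gene-end windows, the alternatives named as added and the closing tests on strong peaks, name stems and multicopy models of X came afterwards. There were 16 lists and 4 gene families, 20 in all: undifferentiated and differentiating spermatogonia, meiotic prophase, spermiogenesis, piRNA pathway, cohesin and CTCF, pluripotency, testis somatic and feeder cells, endothelial and blood cells, somatic lineage regulators, Hox, imprinted, X-linked germline, somatic effector, housekeeping, DNA methylation and Polycomb machinery, receptors, histones, protocadherins and ribosomal proteins. Some genes stand in more than 1 list. H1f9, Pramex1 and Ela2 found no match, Meiosin matched as Bhmg1, and Dnmt3c matched a pseudogene with no peak at its ends. The family rule for ribosomal proteins also takes Rps19bp1, which is not one. Each list was set against all other protein-coding genes with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 20 lists at 0.05. The p-value of the receptor list was too small for the software to hold and is not printed.

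Named genes were every cohesin and CTCF gene; per other list, the 4 with the highest mean percentile of fold, the first 4 alphabetically with no gene-end peak, and up to 4 with one in a single library; the 10 genes with most distal regions; genes at the 10 widest domains; and the 5 strongest distal and gene-end regions. Some genes that this rule names are not reported here. Distal regions touched no gene-end window and were counted within 50 kb of either gene end. Each list's median count was placed among 10000 seeded random lists of the same size, matched on gene-end status. X was compared with the autosomes by a two-sided Fisher's exact test. With 1 group there was no comparison between groups.

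Alternatives were a −log10 q of at least 5, the 50000 peaks of highest fold, reciprocal overlap of 50%, each library alone, a 500 bp window, 100 kb for distal regions, and merging within 1000 bp. Added after the data were seen were the 2500 bp window, the peaks above the median fold of their library, random lists matched on gene length, a comparison group without receptor genes, and own peaks of both libraries in the window. On simulated data with 21887 genes, the list test called 85% of 20 lists of 30 genes raised from 65% to 95%, and 0% of 380 unchanged lists. Simulated genes had peaks independently of each other and lists were drawn at random, without the families and clusters of real genes. The 0% is therefore not the rate of false calls in these data. Tag recovery was right for 100% of 3000 simulated peaks. For strong peaks of 1 library, a simulation of equal openness with counting error only called 48798 peaks, and 0 passed the binomial test. The test covered only those with at least the median tags that the other simulated library left uncalled. Their number was not recorded, so the 0 is no rate of false calls. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.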

Results

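Accessible chromatin was profiled by ATAC-seq in mouse GSCs, as the labels abbreviate the cell type, in which Stag3 had been knocked out. Stag3 encodes a stromal antigen subunit of cohesin, the ring complex that holds sister chromatids together and folds interphase chromosomes into loops. The cells carried the Acrosin-EGFP and beta-Actin-EGFP reporters and were sorted for reporter-positive viable cells before transposition. The series held 1 group of 2 libraries, and the wild-type libraries that the design text names as its comparison were not analysed here. The results therefore describe the accessible sites of Stag3 KO GSCs and how far both libraries shared them, and no value below is a difference caused by the knockout.

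Replicate 1 held 107331 peaks covering 41.1 Mb and replicate 2 held 98986 peaks covering 38.2 Mb, a mean of 103158 ± 5901 peaks (SD, n = 2). The median peak was 322 bp wide in replicate 1 and 324 bp wide in replicate 2. The median fold enrichment given by the authors' peak caller was 8.78 and 8.73, and the highest was 41.3 and 42.4. The number of sequenced reads was not given in the sources used here, but the tags stacked at each summit could be recovered from the deposited values. The median summit held 40 tags in replicate 1, with a range of 9 to 849, and 41 tags in replicate 2, with a range of 9 to 907.

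The targeted gene was examined first. Stag3 lies on chromosome 5 at 138272514 to 138312397 of GRCm38. Both libraries had a modest peak at its lower-coordinate end, at 138272379 to 138272958, with a fold enrichment of 6.27 in replicate 1 and 6.72 in replicate 2. These values stood at percentiles 32.2 and 36.1 of their libraries and rested on 19 and 20 tags. The same region lay inside the neighbouring gene Gal3st4, within 1000 bp of its end at 138273057. A stronger region lay inside the Stag3 model at 138279871 to 138280704, with folds of 19.9 and 18.8 and 417 and 422 tags. It covered the end of Gpc2, at 138280026, a gene placed wholly within Stag3. The labels used here do not say which part of Stag3 was removed, so these peaks do not check the knockout.

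**Figure D1:**
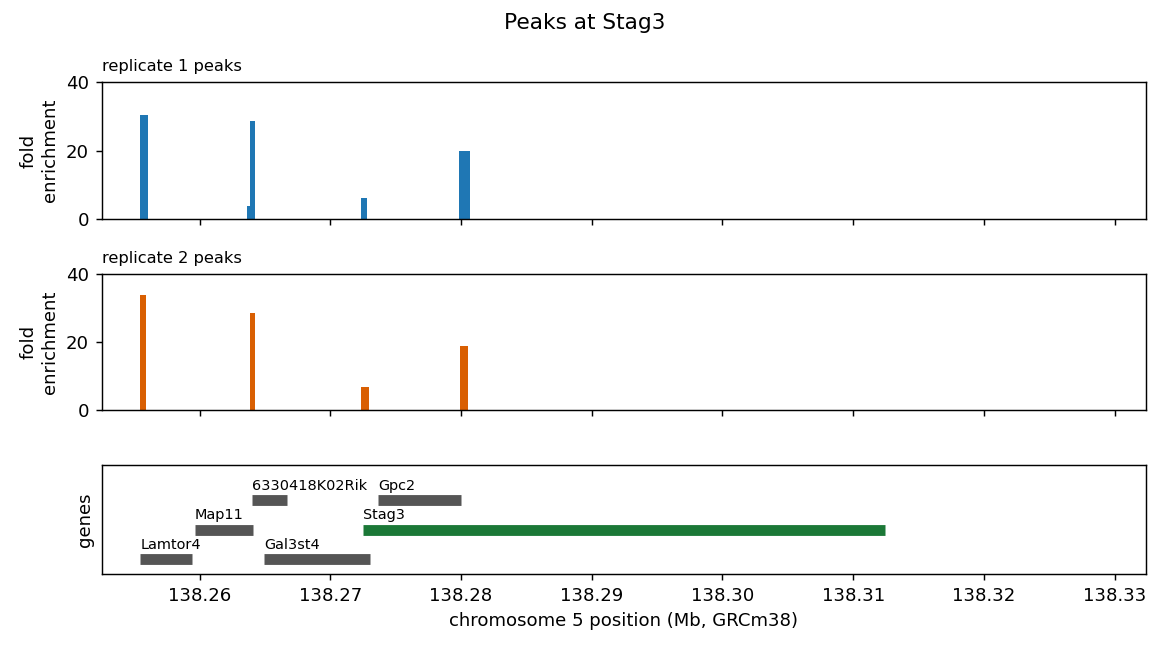
Peaks in the Stag3 region of chromosome 5 in both Stag3 KO libraries, with position in Mb on the x axis, fold enrichment on the y axis and gene spans in the lowest panel (Stag3 in green). The peak at the Stag3 end reached 6.27-fold and 6.72-fold, below the 19.9-fold and 18.8-fold peak at the Gpc2 end.

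Most cohesin and CTCF genes had an accessible site near a gene end in Stag3 KO GSCs. Strand was not used, so such a site may lie at the 3′ end or belong to a neighbour. Of 22 genes, 19 had a region shared by both libraries that reached within 1000 bp of a gene end (86.4%, 95% Wilson interval 66.7 to 95.3), against 65.7% of the other protein-coding genes. The strongest was Rec8, the meiotic kleisin subunit, with 28.2-fold in replicate 1 and 26.8-fold in replicate 2. It was followed by Pds5b (25.6 and 27.8), a regulator of cohesin release, and Wapl (25.9 and 25.9), the release factor itself. The Pds5b region lay near the higher-coordinate end of its gene model. The excess over other genes did not pass the threshold (two-sided Fisher's exact test, adjusted exact p = 0.0670), although it did in 3 of 10 alternatives, among them a window of 2500 bp, where 22 of 22 genes had a peak (adjusted exact p = 0.00315). At Wapl only the replicate 1 peak itself lay in the window, and own peaks of both libraries there were seen at 18 genes (81.8%, adjusted exact p = 0.151).

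Among the stromal antigen genes, Stag1 had folds of 8.78 and 5.90 and Stag2 had folds of 8.75 and 7.93. The ring subunits were higher, with 17.3 and 18.3 at Smc1a, 15.5 and 17.1 at Smc3, 17.7 and 17.4 at the meiotic kleisin gene Rad21l, and 10.1 and 11.9 at the meiotic Smc1b. Ctcf, whose product stops cohesin at loop anchors, had 13.4 and 13.4, and its germline paralogue Ctcfl had 8.06 and 13.6. The loader genes Nipbl and Mau2 had 8.78 and 10.8, and 17.1 and 18.9. The centromere protector Sgo2a had 20.6 and 25.2, the acetyltransferases Esco1 and Esco2 had 12.2 and 14.7, and 20.4 and 21.8, and Cdca5, also called sororin, had 19.8 and 20.1. Pds5a had 14.3 and 13.2. The Nipbl and Sgo2a regions lay wholly outside their gene models.

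The 3 remaining genes had no shared gene-end peak, but each had a strong shared region further inside. Rad21, the mitotic kleisin gene, had a region of 19.98-fold and 19.6-fold on chromosome 15 at 51991591 to 51992105, 1433 bp inside the model. Sgo1 had one of 17.1-fold and 19.2-fold on chromosome 17 at 53688975 to 53689925, 1406 bp inside. Hdac8, the cohesin deacetylase gene, had one of 19-fold and 21.3-fold on chromosome X at 102502749 to 102503299, 2082 bp inside. Its own gene-end peaks, of 3.62-fold in replicate 1 and 4.23-fold in replicate 2, did not overlap each other.

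Most peaks were found in both libraries. In replicate 1, 83732 peaks (78.0%, 95% Wilson interval 77.8 to 78.3) overlapped a replicate 2 peak, and in replicate 2, 84032 peaks (84.9%, interval 84.7 to 85.1) overlapped a replicate 1 peak. Random placement within chromosomes gave 2.96% and 3.21%. Strong peaks recurred more often than weak ones: 99.7% and 99.9% of the highest decile by fold were found again, against 50.7% and 59.9% of the lowest decile. Peaks of 1 library had a median of 19 and 18 tags, against 52 and 50 for shared peaks.

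In 73713 pairs of matching peaks with summits within 100 bp, the summed tags of replicate 2 were 1.03 times those of replicate 1. The squared differences were 3.98 times those of counting error alone, with tags treated as independent. Log2 tags correlated with r = 0.91 across peaks, which are not independent replicates. The labels do not say whether the libraries came from separate cultures, so the spread between them may be technical.

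**Figure D2:**
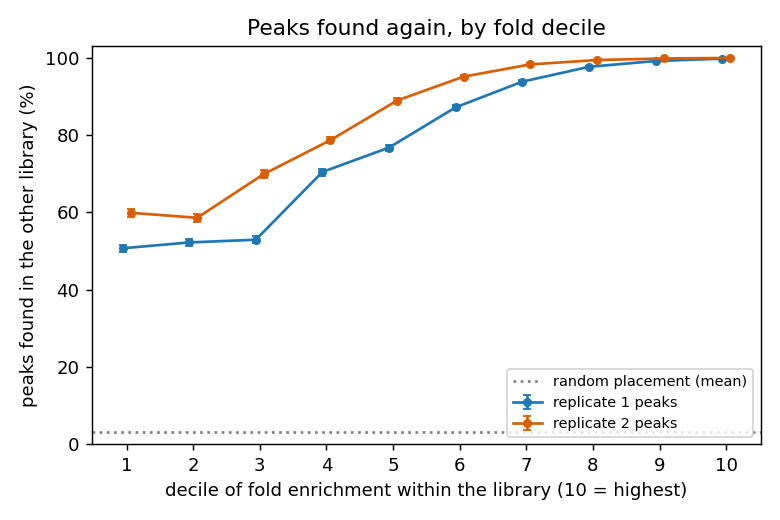
Share of peaks found in the other library (y axis, %) by decile of fold enrichment within the library (x axis, 10 highest), with 95% Wilson intervals and the mean of random placement as a dotted line. Replicate 1 ran from 50.7% in the lowest decile to 99.7% in the highest, and replicate 2 from 59.9% to 99.9%.

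The shared sites were concentrated at the ends of protein-coding genes. Of the 83732 shared regions, 20.8% (95% Wilson interval 20.5 to 21.1) had their summit within 1000 bp of a gene end, 6.65 times the 3.13% of random placement. Protein-coding gene bodies held 37.1%, close to the random 38.5%, other genes held 8.47% against 8.13%, and intergenic sequence held 33.6% against 50.2%. By library, the gene-end share was 17.9% of replicate 1 peaks and 19.4% of replicate 2 peaks (mean 18.7 ± 1.08, SD, n = 2). It moved with the definition, to 15.6% within 500 bp and 28.0% within 2500 bp.

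A shared region reached a gene end, here called a gene-end peak in both libraries, at 14390 of 21887 protein-coding genes (65.7%, 95% Wilson interval 65.1 to 66.4), against 14.7% under random placement. At 48 of these genes the peak of 1 library alone lay in the window and its partner outside, so that 14342 had own peaks of both libraries there. Replicate 1 alone gave 67.6% and replicate 2 alone 67.3% (mean 67.5 ± 0.252, SD, n = 2). Another 704 genes had a peak there in 1 library only, 46 had peaks of both that did not overlap, and 6747 had none. The windows cover both ends and reach beyond the gene, so a gene-end peak may be a 3′ site or belong to a neighbour. The best regions of Akap3 and Rpl3l, for example, lay wholly outside the gene model. A gene with none may still be open at a start site inside its model, which these windows miss. The strongest gene-end regions were those of the zinc finger gene Zfp691 (chromosome 4 at 119174074 to 119174511, 38.1-fold and 38.7-fold) and of Mcm3, a subunit of the replicative helicase (chromosome 1 at 20820156 to 20820623, 37.1-fold and 38.0-fold). The next were at Cyb561a3 and Tkfc on chromosome 19 (36.6 and 38.2), Zfp157 on chromosome 5 (36.2 and 38.3) and Zfp640 on chromosome 13 (36.5 and 37.5).

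Genes of undifferentiated spermatogonia and of meiotic prophase had gene-end peaks more often than other genes. Each of the 32 genes of undifferentiated spermatogonia had one in both libraries (100%, interval 89.3 to 100, adjusted exact p = 1.29e-05), among them Id4 (21.0-fold and 23.3-fold), a marker of stem cell activity, Epcam (23.2 and 21.1), Taf4b (19.3 and 23.4) and Sall4 (19.985 and 22.4). Of 43 genes of meiotic prophase, 41 had one (95.3%, interval 84.5 to 98.7, adjusted exact p = 3.02e-05), led by the axis gene Hormad2 (32.2 and 32.7), Terb2 (29.5 and 31.2), Mei4 (29.1 and 30.7) and Syce3 (27.6 and 31.8), a central element gene of the synaptonemal complex. Fkbp6 had none and Hsf2bp had one in replicate 2 only. When only peaks above the median fold of their library counted, the undifferentiated list was no longer set apart, at 56.3% against 51.9% of other genes (adjusted exact p = 0.762), whereas the meiotic list still was, at 79.1%.

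Other germline lists did not differ from the remaining genes at the threshold of 0.05. Of 20 genes of differentiating spermatogonia, 18 had a gene-end peak (90%, adjusted exact p = 0.0510), with Rec8, Sohlh2 (22.8 and 23.9), Dmrt1 (17.5 and 22.1) and Stra8 (15.1 and 18.3), the retinoic acid target at meiotic entry. Rarb had none and Nxf3 had one in replicate 1 only. The list passed in 5 of 10 alternatives, with the lowest adjusted exact p in replicate 1 alone (0.0200). With the 50000 strongest peaks and above the median fold it fell to 45.0%, below the 50.8% and 51.9% of other genes (adjusted exact p = 0.776 and 0.762). In the piRNA pathway, 18 of 24 genes had one (75%, adjusted exact p = 0.440), among them Rnf17 (28.7 and 33.2), Tdrd12 (30.1 and 29.2), Gtsf1 (27.7 and 28.2) and Tdrkh (21.7 and 24.7), while Piwil1, Piwil2, Tdrd9 and Fkbp6 had none. Tdrd7 and Tex19.1 had one in a single library.

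Spermiogenesis genes, used in haploid cells, had a gene-end peak in 18 of 35 cases (51.4%, adjusted exact p = 0.0966). Akap3 (31.3 and 28.6), Gapdhs (26.5 and 30.2), Catsper2 (16.8 and 16.7) and Tekt1 (16.0 and 17.0) had the strongest, and Catsper1, Catsper3, H1f7 and Oaz3 were among the 13 with none. Acrv1, Akap4, Pgk2 and Tssk2 had one in replicate 1 only. Of 26 pluripotency and early germ cell genes, 21 had a gene-end peak (80.8%, adjusted exact p = 0.172), with Dppa5a (30.3 and 31.3), Dnd1 (26.2 and 24.5), Klf5 (23.9 and 26.3) and Tfcp2l1 (21.4 and 21.4). Esrrb, Lefty1, Lefty2 and Pou5f1 had none. Of 26 X-linked germline genes, 16 had one (61.5%, adjusted exact p = 0.681), led by Tex11 (29.2 and 29.6), Usp26 (25.4 and 29.8), Xlr (25.9 and 28.4) and Rbmx (24.8 and 24.6), while Mageb4, Ott, Rhox1 and Slx had none.

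Developmental regulators of somatic tissues often had a gene-end peak, but seldom one above the median fold of its library. Fold is relative to the local background, and tags at these genes were not compared with those of other genes. How open these sites were was therefore not measured. Of 35 somatic lineage regulators, 30 had a gene-end peak in both libraries (85.7%, interval 70.6 to 93.7, adjusted exact p = 0.0281), from Mitf (34.3 and 36.6) through Trp63 (19.12 and 18.2), Isl1 (16.9 and 17.6) and Eya1 (14.8 and 19.2). Of 39 Hox genes, 33 had one (84.6%, interval 70.3 to 92.8, adjusted exact p = 0.0281), led by Hoxc13 (21.4 and 21.4), Hoxb13 (18.0 and 19.9), Hoxc10 (12.9 and 17.7) and Hoxd1 (15.4 and 12.1). Among peaks above the median fold the direction turned: 28.6% of the lineage regulators (adjusted exact p = 0.0253) and 28.2% of the Hox genes (adjusted exact p = 0.0174) had one, below the 52.0% of other genes. With a −log10 q of at least 5 the lineage regulators no longer passed (82.9%, adjusted exact p = 0.0536). Hnf4a, Myf5, Runx1, Hoxa9, Hoxb3 and Hoxd9 had no gene-end peak, and Tbx5, Hoxb1, Hoxc4 and Hoxd4 had one in 1 library.

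Genes for the products of differentiated somatic cells had few gene-end peaks. Of 33 somatic effector genes, 13 had one (39.4%, interval 24.7 to 56.3, adjusted exact p = 0.0106), and Actc1, Alb, Amy2b and Fabp1 were among the 19 with none. The exceptions included Scgb1a1 (32.1 and 30.4), Ckm (29.7 and 32.0), Syn1 (14.8 and 18.96) and Krt10 (16.0 and 16.7), and Krt14 had one in replicate 2 only. The Scgb1a1 region lay wholly outside the gene model, and the Ckm region lay at the higher-coordinate end. Of 1465 olfactory and vomeronasal receptor genes, 26 had one (1.77%, interval 1.21 to 2.59, odds ratio 0.00762), with Olfr98 (22.9 and 26.2), Vmn1r1 (22.6 and 24.0), Olfr286 (19.6 and 23.9) and Vmn1r222 (19.8 and 19.9) at the top. The regions of Olfr98, Vmn1r1 and Olfr286 lay wholly outside their gene models. Strand was not used, so these regions may be 3′ sites or belong to neighbours. With the 50000 peaks of highest fold per library, the somatic effector list no longer passed (30.3%, adjusted exact p = 0.0564).

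Markers of other cell types that a sort could carry over did not pass the threshold. The test compares their share with that of other genes, so it cannot show whether such cells were present. Of 31 genes of testis somatic and feeder cells, 18 had a gene-end peak (58.1%, adjusted exact p = 0.472), including Acta2 (27.2 and 25.7), Cyp11a1 (24.6 and 27.1), Col1a1 (14.1 and 15.4) and Dhh (13.5 and 15.3), whereas Amhr2, Col3a1, Dcn and Gata4 had none and Rhox5 had one in replicate 2. Of 22 endothelial and blood cell genes, 10 had one (45.5%, adjusted exact p = 0.0939), including Spi1 (21.5 and 21.1), Csf1r (20.9 and 20.8), Kdr (15.4 and 16.0) and Erg (14.4 and 15.9). The Csf1r and Erg regions lay wholly outside their gene models. Spi1 had its region near the higher-coordinate end and Kdr near the lower. Strand was not used, so any of these may be a 3′ site or belong to a neighbour. Adgre1, Emcn and Gata1 had none and Cdh5 had one in replicate 2.

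In the main setting, broadly expressed and chromatin genes had gene-end peaks more often than other genes. Of these lists, only the ribosomal one stayed higher in all 10 alternatives. Ribosomal protein genes had a gene-end peak in 78 of 85 cases (91.8%, interval 84.0 to 96.0, adjusted exact p = 2.89e-07), with Rpl3l (30.7 and 34.6), Rps19bp1 (28.5 and 27.2) and Rps26 (27.5 and 28.1). Housekeeping genes had one in 26 of 30 (86.7%, adjusted exact p = 0.0368), led by Pgk1 (25.7 and 28.2), Hprt (24.5 and 26.0), Canx (24.0 and 25.9) and Atp5b (24.2 and 25.5). Ldha, Pcna, Rpl13a and Ywhaz had none, so having none does not mark a gene as inactive. Genes of DNA methylation and Polycomb machinery had one in 25 of 28 (89.3%, adjusted exact p = 0.0278), led by L3mbtl2 (29.1 and 27.7), Max (23.7 and 26.0), Setdb1 (21.8 and 26.7) and Cbx2 (20.1 and 20.3). Cbx7 and Dnmt3a had none and Dnmt1 had one in replicate 2 only.

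Imprinted genes had a gene-end peak in 23 of 26 cases (88.5%, adjusted exact p = 0.0281), led by Zim1 (35.6 and 35.9), Ndn (27.5 and 26.3), Mcts2 (22.4 and 25.5) and Inpp5f (23.2 and 23.2), and Igf2, Mest and Snrpn had none. The list no longer passed above the median fold (57.7% against 51.9% of other genes, adjusted exact p = 0.762). With the 50000 strongest peaks its share was 50.0% against 50.8%. Among noncoding imprinted genes, Kcnq1ot1 had 21.6 and 22.4, H19 had 23.8 and 11.04, Airn had 6.44 and 10.1, and Meg3 had a peak in replicate 1 only. Clustered histone genes had one in 53 of 67 cases (79.1%, adjusted exact p = 0.0368), led by H3c15 (26.5 and 28.4), but no longer passed above the median fold (56.7% against 51.9% of other genes, adjusted exact p = 0.619) or with the 50000 strongest peaks (52.2% against 50.8%, 0.950). Clustered protocadherin genes had one in 44 of 57 (77.2%, adjusted exact p = 0.0939), led by Pcdhgc3 (22.7 and 24.1) and Pcdhac1 (22.4 and 22.3).

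In all, 9 of the 20 lists were higher, 2 were lower and 9 did not pass. These tests compare genes within the same libraries, and genes are not independent replicates. The comparison group also holds predicted gene models and large families. Leaving these out on every chromosome alike, 80.4% of 14122 autosomal genes had a gene-end peak, and no list was tested against that set. The receptor genes weighed on the comparison group: without them, its share rose to 70.3% while the shares of the other lists did not change, only the undifferentiated, meiotic and ribosomal lists stayed higher, and adjusted p for the other 6 lay between 0.0972 (DNA methylation and Polycomb machinery) and 0.205 (clustered histones). Within 500 bp of gene ends, 4 of the 9 no longer passed: somatic lineage regulators (74.3%, adjusted exact p = 0.218), Hox genes (74.4%, 0.217), imprinted genes (76.9%, 0.218) and DNA methylation and Polycomb machinery (82.1%, 0.0617). There the differentiating spermatogonia list was higher (90%, adjusted exact p = 0.0240) and the endothelial and blood cell list lower (31.8%, 0.0222). Within 2500 bp, imprinted genes (adjusted exact p = 0.112), DNA methylation and Polycomb machinery (0.0997) and histone genes (0.112) no longer passed, while protocadherins (0.00252) did.

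**Figure D3:**
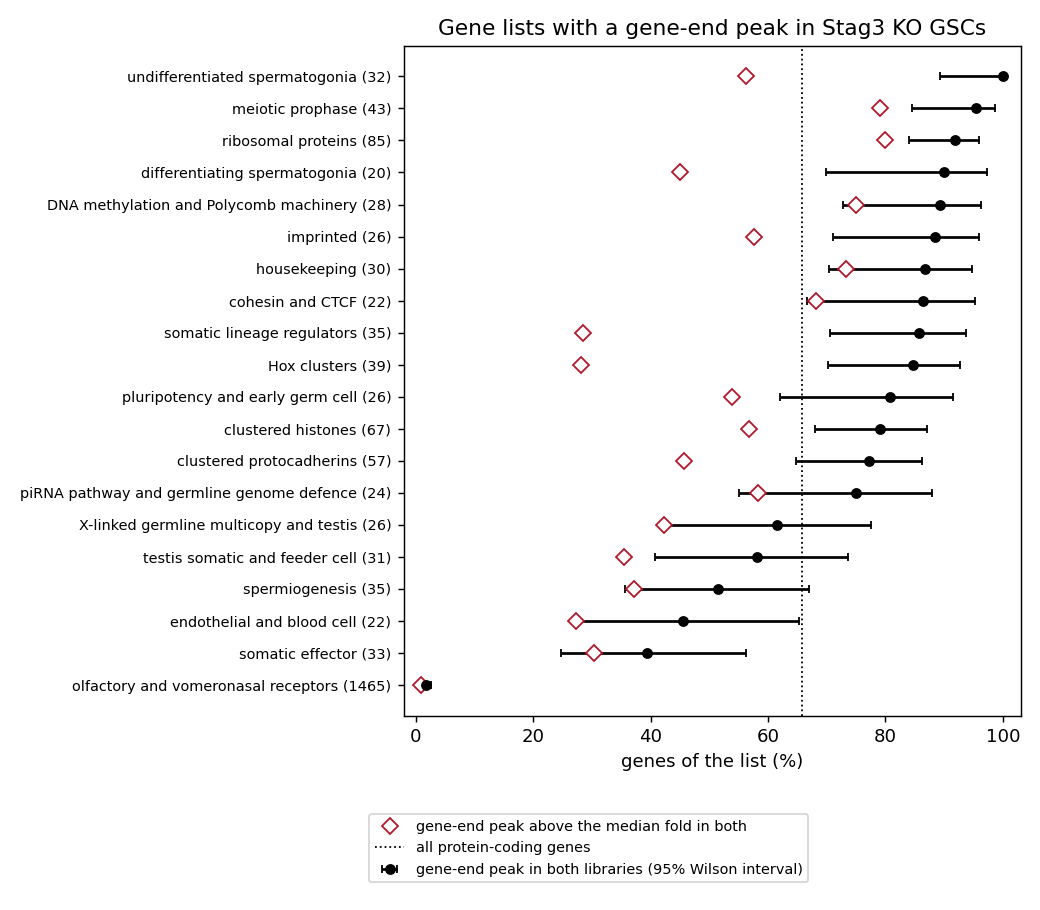
Share of the genes of each list (x axis, %) with a gene-end peak in both libraries, with 95% Wilson intervals (black), and with such a peak above the median fold in both (red diamonds); the number of genes follows each name and the dotted line marks the 65.7% of all protein-coding genes. Hox genes and somatic lineage regulators fell from 84.6% and 85.7% to 28.2% and 28.6%, where other genes had 52.0%. The dotted line applies to the black points only.

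Of the 20 lists, Hox and protocadherin genes had the most shared regions away from gene ends. The median Hox gene had 11 shared distal regions within 50 kb of its ends, against 4 in random lists matched on gene-end status, and lay at percentile 100 of 10000 such lists. Protocadherin genes also had 11 against 4 (percentile 100). Medians of 7 were seen for pluripotency genes (percentile 99.5), somatic lineage regulators (99.6), DNA methylation and Polycomb machinery (99.4) and undifferentiated spermatogonia (99.2), and histone genes had 6 (98.9). Receptor genes had 0 (percentile 0). Members of a cluster share regions, so their counts are not independent. Within 100 kb, only the Hox, protocadherin, histone and pluripotency lists stayed above the central 95% of random lists.

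Single genes with the most distal regions within 50 kb were Sptbn4 with 33 and Ryr1 with 29, both on chromosome 7, then Btn2a2 with 28 and Btn1a1 with 27, neighbours on chromosome 13. Shkbp1, Mtus2, Tacc1 and the predicted gene Gm38667 had 25, and Chst8 and Gm38666 had 24. The distal regions with the highest folds lay within Gm31714 on chromosome 13 at 65415021 to 65415386 (39.97 and 42.4), and 57959 bp from Tmem182 on chromosome 1 at 40914847 to 40915257 (41.3 and 39.7). Others lay 17322 bp from Zfp640 (40.8 and 39.4), 8329 bp from Scgn (38.9 and 40.5) and 83361 bp from Sorcs3 (38.5 and 40.04).

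Shared regions merged within 500 bp formed 73748 domains with a median width of 413 bp, and 212 were wider than 2 kb. The widest, of 3554 bp, lay on chromosome 9 at 124422441 to 124425994 at the predicted genes Gm20783 and LOC108167694. Next came 3209 bp at Bhlhe40, a circadian repressor gene, on chromosome 6 at 108658607 to 108661815. Spaca6 (3041 bp), Foxe1 (2931 bp), Gse1 (2923 bp), Csf2ra (2779 bp), Arid1b (2759 bp) and Clasp1 (2722 bp) also lay in the 10 widest. Another of 3086 bp lay 15405 bp from Osbp, and one of 3064 bp lay within Cpeb2. Domains were not screened for assembly gaps, and merging within 1000 bp put a domain of 4117 bp at Ssbp3 first.

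Chromosome X carried fewer accessible sites than any autosome. It held 12.7 shared regions per Mb against 33.4 on the autosomes together, a ratio of 0.380, while the autosomes ranged from 25.4 on chromosome 14 to 43.1 on chromosome 11. The ratio was 0.404 in replicate 1 and 0.369 in replicate 2. X also had fewer genes per Mb, 0.669 times the autosomal density. Of 966 X-linked protein-coding genes, 529 had a gene-end peak in both libraries (54.8%), against 13853 of 20665 autosomal genes (67.0%; two-sided Fisher's exact test across genes, p = 1.25e-14). Leaving out predicted gene models, and families with 5 or more genes on a chromosome, on every chromosome alike, the shares were 72.7% of 553 X-linked genes and 80.4% of 14122 autosomal genes (exact p = 2.14e-05). Leaving out predicted gene models and, of the families, only those repeated on X, which keeps most autosomal families, brought the autosomal share to 73.7% (exact p = 0.589).

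**Figure D4:**
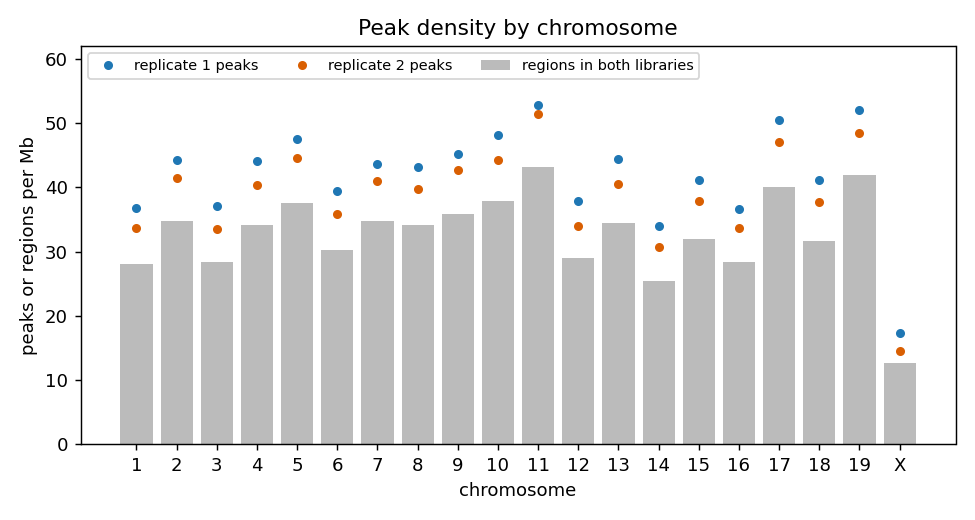
Shared regions (bars) and peaks of each library (points) per Mb (y axis) on each autosome and X (x axis) in Stag3 KO GSCs. X, at 12.7 shared regions per Mb, lay below the lowest autosome, chromosome 14, at 25.4.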

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

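No test was run on the Y chromosome, which stood outside the comparisons of the report. Replicate 1 held 78 peaks on Y and replicate 2 held 61. Both libraries shared 52 regions there, and 8 of 256 Y-linked protein-coding genes had a gene-end peak in both. They were Uba1y (33.5-fold in replicate 1 and 36.5-fold in replicate 2), Usp9y (29.2 and 32.5), Uty (28.3 and 29.2), Ddx3y (24.5 and 30.8), Eif2s3y (15.9 and 18.5), Zfy1 (9.09 and 16.3), Kdm5d (8.78 and 5.76) and Gm52481 (4.12 and 3.58).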

How the results depend on the processing

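The alternatives with a 2500 bp window, peaks above the median fold, length-matched random lists, a comparison group without receptor genes and own peaks of both libraries in the window were chosen after the data were seen. No paired analysis was possible because the series as used here holds 1 group only. Motif shares, transcription start windows and 5′-end starts were not run, since sequence and start sites were not used here. The number of protein-coding genes with a gene-end peak stayed within 1.5 times 14390 throughout, from 11112 with the 50000 strongest peaks to 15840 at 2500 bp. The X to autosome ratio stayed between 0.364 and 0.404.

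The share of replicate 1 peaks found again rose to 83.9% with the 50000 strongest peaks, and with reciprocal overlap the shares fell to 73.4% of replicate 1 and 79.6% of replicate 2 peaks. The gene-end share of regions was 23.7% with the 50000 strongest peaks, 15.6% at 500 bp, 28.0% at 2500 bp, and 17.9% to 19.4% with either library alone. Higher lists numbered 4 with the 50000 strongest peaks, 2 among peaks above the median fold and 3 without receptor genes, against 9; lower lists numbered 4 above the median fold, against 2. Without receptor genes 1 was lower, because the receptor list itself was left out, and somatic effector genes stayed lower (39.4%, adjusted exact p = 0.00167). With the 50000 strongest peaks, the share turned below that of other genes for somatic lineage regulators (25.7%, adjusted exact p = 0.0175), Hox genes (28.2%, 0.0233), imprinted genes (50.0%, 1), differentiating spermatogonia (45.0%, 0.776) and protocadherins (45.6%, 0.677). Above the median fold it did so for lineage regulators (28.6%, adjusted exact p = 0.0253), Hox genes (28.2%, 0.0174), differentiating spermatogonia (45.0%, 0.762) and protocadherins (45.6%, 0.508). Protocadherins also turned lower with reciprocal overlap (63.2%, adjusted exact p = 1), and X-linked germline genes, at 65.4% to 76.9% with either library alone, turned higher without replicate 2 (0.424). The cause was not tested further. Lists above random in distal regions fell from 7 to 4 within 100 kb. Lists below numbered 2, against 1, within 100 kb, with reciprocal overlap and with length matching, and 1 to 2 with either library alone.

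Meiotic prophase (adjusted exact p at most 0.00223) and ribosomal proteins (at most 0.000107) stayed higher in all 10 alternatives. With own peaks of both libraries in the window, 14342 genes counted, DNA methylation and Polycomb machinery stayed higher (85.7%, adjusted exact p = 0.0454) and differentiating spermatogonia passed (0.0364). Within 500 bp, somatic lineage regulators (adjusted exact p = 0.218), Hox genes (0.217), imprinted genes (0.218) and DNA methylation and Polycomb machinery (0.0617) no longer passed. Within 2500 bp, imprinted genes (adjusted exact p = 0.112), DNA methylation and Polycomb machinery (0.0997) and histone genes (0.112) did not. With a −log10 q of at least 5, lineage regulators (82.9%, adjusted exact p = 0.0536) did not. With the 50000 strongest peaks, undifferentiated spermatogonia (56.3%, adjusted exact p = 0.747), somatic effector (30.3%, 0.0564) and histone genes (52.2%, 0.950) no longer passed. Above the median fold, undifferentiated spermatogonia (adjusted exact p = 0.762), imprinted (57.7%, 0.762), housekeeping (73.3%, 0.0664), DNA methylation and Polycomb (75%, 0.0612) and histone genes (56.7%, 0.619) did not. Without replicate 1, housekeeping (0.0555) and histone genes (0.0578) no longer passed. Without replicate 2, DNA methylation and Polycomb machinery (0.0575) no longer passed, while differentiating spermatogonia (0.0200), cohesin and CTCF (0.0421) and protocadherins (0.0392) did.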

Other observations

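The tests on strong peaks of 1 library, on gene families by name and on multicopy models of X were chosen after the result was seen. Protein-coding genes grouped by the stem of their symbol gave 78 groups of at least 25 genes, of which 35 had gene-end peaks more often than other genes and 23 less often (two-sided Fisher's exact test, adjusted over the groups). Zinc finger genes named Zfp had one in 334 of 397 cases (84.1%, adjusted exact p = 2.34e-15). Translation initiation factor genes named Eif had one in 53 of 56 (94.6%, adjusted exact p = 2.93e-06), the Rab genes of vesicle traffic in 63 of 69 (91.3%, adjusted exact p = 6.26e-06), and the Med genes of the Mediator complex in 29 of 30 (96.7%, adjusted exact p = 0.000191).

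The groups named here were picked from both ends after their values were seen. Keratin-associated protein genes (Krtap) had a gene-end peak in 3 of 56 cases (5.36%, adjusted exact p = 4.11e-20), Pramel genes in 3 of 47 (6.38%, adjusted exact p = 2.78e-16), and Defa and Prl genes in 0 of 29 and 0 of 26 (adjusted exact p = 3.45e-13 and 6.72e-12). Cytochrome P450 genes (Cyp) had one in 30 of 99 (30.3%, adjusted exact p = 6.90e-12). The X-linked Rhox homeobox genes had one in 9 of 33 (27.3%, adjusted exact p = 3.37e-05). Many of these genes lie in clusters, so members are not independent.

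Some strong peaks appeared in 1 library only. Among peaks in the upper deciles by fold, 6 to 10, replicate 1 had 2458 with no partner and replicate 2 had 764. The strongest in replicate 1 lay 32799 bp from Tram1 on chromosome 1 at 13531531 to 13531893 (30.9-fold, 145 tags), and the strongest in replicate 2 lay 47540 bp from Prkg2 on chromosome 5 at 99084916 to 99085332 (35.5-fold, 259 tags), followed by peaks 40300 bp from Prox1 (34.3-fold) and 262033 bp from Sox9 (33.9-fold). Strong 1-library peaks seldom lay at gene ends: 2.81% and 4.32% did, against 21.2% and 22.6% of shared strong peaks (Fisher's exact test across peaks, p = 4.80e-154 and 1.74e-44). The sets were not matched on tags. The 1-library peaks had medians of 33 and 32 tags, while shared autosomal peaks had 87 and 93 at gene ends and 47 and 43 elsewhere. How far tag number accounts for the difference was not tested. In peaks called in both libraries, 183 had over 4 times the tags in replicate 1 and 41 in replicate 2, and 8 of these lay at gene ends, while at 50 tags or more in both the SD of the log2 ratio was 0.27 at gene ends and 0.40 elsewhere.

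Sampling of tags at equally open sites could leave a peak in 1 library, and 91.2% of these peaks in replicate 1 and 57.5% in replicate 2, 83.2% together, had more tags than the highest count the other library could hold uncalled allows (exact binomial test, adjusted over all peaks of the library). That test covers counting error only, though squared differences of matching peaks were 3.98 times as large, and it largely restates the choice of peaks with at least 27 tags and no partner, so sampling stays open. A lower depth or enrichment throughout the library without the peak is argued against by summed tags of matching peaks away from gene ends, 0.996 times as many in replicate 2 (0.968 to 1.04 by autosome), where losing the median such peak takes a 3.67-fold or 3.88-fold drop, and by such peaks in both libraries. The median log2 ratio of replicate 2 over replicate 1 was 0.14 at gene ends and −0.03 elsewhere, so the libraries differed by kind of site, and whether this bears on the larger number in replicate 1 stays open. What made distal sites differ stays open, and no biological explanation was tested, since the labels give 1 group.

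The low density of X was weighed against copy number, and the lower share of its genes with a gene-end peak against annotation. A single X in male cells may halve its tags, and the 90th percentile of tags at shared gene-end peaks on X was 0.705 of the autosomal value (0.700 in replicate 1, 0.710 in replicate 2), between the bounds of 0.65 and 0.8 set before this percentile, though not the medians of all shared peaks, had been seen. The medians at these peaks were 0.793 and 0.828 of the autosomal ones, on both sides of 0.8, with medians elsewhere of 40 tags against 47 in replicate 1 and 34 against 43 in replicate 2, and copy number therefore cannot be told apart from other causes of the lower density. The lower share of genes could come from multicopy and unnamed gene models. Leaving these out on every chromosome alike, 413 of them on X, narrowed the gap from 12.3 to 7.68 percentage points, between the bounds of 3 and 8, so that such models may account for part of it while the rest stays open.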
